A study of Mus musculus with 9 samples.

How the data were processed

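Messenger RNA was measured on Affymetrix MoGene 2.0 arrays, each hybridised with RNA of 1 culture of mouse embryonic fibroblasts. The 9 arrays cover 3 genotypes and 3 treatments, with 1 array per genotype and treatment. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, and 300 ng per sample was amplified and labelled with the GeneChip WT PLUS reagents. The authors deposited 1 log2 signal per probe set and array. Per the submitters' processing notes, these values were made with Affymetrix Expression Console 1.3.1.187, and the background correction, normalisation and summarisation methods are not given in the sources used here. The deposited log2 values had nearly equal medians on all arrays, between 4.42 and 4.46, and no further scaling was applied. The log2 scale was read from the range of the values. No detection calls were used here, so a low signal cannot be told from background, and differences between low signals understate the change of a transcript.

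Each array carried 41345 probe sets. The platform table names 1 gene symbol for 23521 of them, several symbols for 1814 and none for 16010. Of the probe sets with 1 symbol, 23328 matched the RefSeq gene table of assembly GRCm38.p6 by gene identifier, and this table was used only for names and for the chromosome and order of genes. A gene took the probe set with the highest mean over the 9 arrays, which gave 22180 genes, 1082 of which had more than 1 probe set. Probe sets with several symbols or none stayed out of the comparisons, and this left out some interferon-inducible genes, which are not analysed here. Probe sets of recently duplicated families (Ifi200, Ifit, Gbp, Oas and chemokine genes) can also read transcripts of their relatives, so values of single members are uncertain. The sources used here name no genome build for the probe sets, and no coordinates are given.

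Differences between 2 arrays are differences of log2 signals. A gene was counted when the brighter array was at or above 4.44, the median of all values, and the difference was at least 1 on the log2 scale, which is 2-fold. Such a difference rests on 1 array on each side. Overlaps and correlations of the responses of 2 genotypes use the genes at or above 4.44 on at least 1 of the 4 arrays involved, so their counts of genes up can exceed those of a single comparison. Tests used limma 3.58.1 in R 4.3.3, with lmFit, eBayes with an intensity trend and Benjamini-Hochberg adjustment over 14737 genes at or above 4.44 on at least 1 of the 9 arrays, at an adjusted p under 0.05. An array with an induced gene can thus decide that this gene is tested. The response model held the genotypes, a dsDNA effect shared by the STING-sufficient genotypes (WT and MyD88KO), a dsDNA effect of SKO, an LPS effect shared by the MyD88-sufficient genotypes (WT and SKO) and an LPS effect of MyD88KO. It left 2 residual degrees of freedom, and the spread it estimates is the difference in response between genotypes that share an effect. Because effects are shared, a fitted value can lie outside the range of the array differences it summarises. The genotype model held genotype and treatment as additive terms with 4 residual degrees of freedom, and a gene was called at an adjusted p under 0.05 and at least 2-fold. List counts in its comparisons are given at an adjusted p under 0.05 at any size, where stated with the members also at least 2-fold. The labels do not say whether the arrays of a genotype came from separate preparations of cells, so the p-values measure the spread between these arrays. The labels give no batch, and the number of arrays limits the precision.

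For 23 gene lists the median log2 difference was set against 10000 random lists of equal size, matched on mean expression in 20 bins, and the percentile describes these arrays only. The lists cover interferon genes, interferon-stimulated genes, interferon-inducible GTPases, chemokines, NF-kB target genes, antigen presentation, Toll-like receptor pathway components, cytosolic nucleic acid sensing components, immediate early genes, the integrated stress and unfolded protein response, p53 target genes, proliferation genes, cholesterol biosynthesis genes, glycolysis and hypoxia genes, sex-linked genes, and markers of fibroblasts and extracellular matrix, leukocytes and macrophages, epithelium, endothelium, muscle, neural and glial cells, chondrocytes and osteoblasts, and adipocytes. The samples of each group, the comparisons, the models, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule names 12 genes always. It adds, for each shared response, the 12 largest mean rises and up to 6 falls among genes past 2-fold in both genotypes. For each difference of response it adds the 8 largest positive and the 4 largest negative values among those that passed, or by size where fewer passed, and for the lone knockout the 5 largest rises and 3 falls past 2-fold. It adds 6 genes each way for dsDNA against LPS in WT, 8 each way for each knockout against WT among genes called and 2-fold apart under all 3 treatments, and up to 4 members of each list per comparison with the largest absolute difference. Predicted, RIKEN and small RNA genes were counted but not named.

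The fits were tested on simulated arrays made from the real means and spreads of 14737 genes. For the shared dsDNA response, 100% of genes set to log2 changes of 1 and 100% of those set to 2 were recovered, and 29 unchanged genes were called. For the difference of the dsDNA responses 88% and 100% were recovered with 37 unchanged genes called, and for SKO against WT, at log2 changes of 1.5 and 2, 100% of both sets were recovered with 0 unchanged genes called. In the response model the simulated share of false calls was thus above the nominal 0.05, and its calls near the threshold are uncertain. Alternative settings were a shift of each array to a common median, cyclic loess, no dim filter or a filter at 6.42 (the 75th percentile), the mean of a gene's probe sets, a 1.5-fold threshold, eBayes without trend, an additive average over the genotypes, members past the dim filter for list medians, and fits without single arrays. Robust eBayes and fits without the SKO mock array were added after the data were seen. Fits without the WT LPS, the SKO LPS or the SKO mock array leave the same difference between genotypes as spread. Equal counts among them are therefore not separate checks. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.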

Results

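Transcript levels were measured in fibroblasts isolated from mouse embryos of 3 genotypes. These were wild type (WT) cells, cells without STING (SKO), the membrane adaptor that relays the detection of DNA in the cytosol, and cells without MyD88 (MyD88KO), an adaptor of most Toll-like receptors and of the interleukin 1 receptor. Cells of each genotype were transfected with double-stranded DNA (dsDNA, labelled ISD), treated with lipopolysaccharide (LPS), the bacterial ligand of Toll-like receptor 4, for 6 h, or left as a mock control. The titles call the control mock and the protocol calls it untreated, and whether it received transfection reagent is not given in the sources used here. Differences between dsDNA and mock may therefore include an effect of the transfection itself. Each of the 9 combinations was measured on 1 array, and differences between 2 arrays therefore have no replicate check. Values are log2 signals, on which a difference of 1 is 2-fold.

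The targeted genes were examined as a check of the genotype labels. Sting1, which encodes STING, had log2 signals of 8.54, 8.57 and 8.54 in the WT mock, dsDNA and LPS arrays and of 8.73, 9.32 and 8.87 in MyD88KO. In SKO its signals were 4.54, 4.60 and 3.78, and over the 3 treatments it was lower in SKO than in WT by a log2 difference of -4.24 ± 0.18 (SE; limma adjusted p = 0.000179; lower in 3 of 3 treatments). Myd88 did not pass the test in MyD88KO, with signals of 6.99, 8.21 and 7.17 against 7.52, 8.95 and 7.73 in WT (log2 difference -0.61 ± 0.19, limma adjusted p = 0.0613). The part of the Myd88 transcript that the probes read is not given in the sources used here and may lie outside the deleted part, so Myd88 does not check the MyD88KO labels. The growth protocol and the series design write MyD99KO where the titles and genotype labels write MyD88KO, and the titles were followed here without a check from expression. Tlr4, the receptor of LPS, had signals between 5.04 and 5.75 on all arrays.

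**Figure D1:**
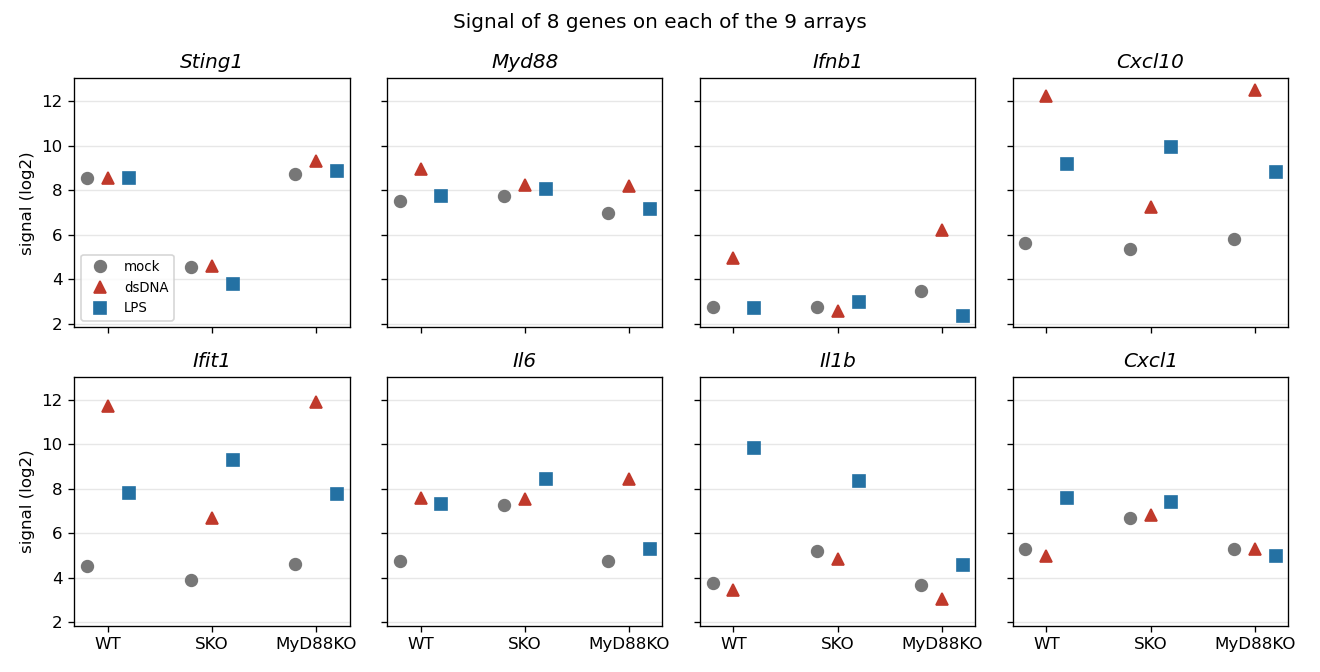
Log2 signal (vertical axis) of 8 genes on each of the 9 arrays, by genotype (horizontal axis) and treatment (grey circles mock, red triangles dsDNA, blue squares LPS), with 1 array per point. Sting1 lay between 3.78 and 4.60 in SKO and between 8.54 and 9.32 elsewhere, Cxcl10 with dsDNA reached 12.25 in WT, 12.53 in MyD88KO and 7.25 in SKO, and Il1b with LPS reached 9.84 in WT, 8.36 in SKO and 4.57 in MyD88KO.

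Transfected dsDNA raised interferon-inducible genes in WT and MyD88KO cells. Cmpk2, a nucleotide kinase gene induced by interferon, rose by 7.45 in WT and 7.70 in MyD88KO (shared response 7.69 ± 0.19 SE, limma adjusted p = 7.5e-06). Ifit1, whose product binds foreign RNA, rose by 7.21 and 7.28, and the chemokine genes Cxcl10 and Ccl5, whose products attract T cells, rose by 6.62 and 6.71 and by 5.90 and 6.61. Ifnb1, the interferon beta gene, went from 2.74 to 4.96 in WT and from 3.49 to 6.21 in MyD88KO (shared response 2.48 ± 0.17, limma adjusted p = 0.00049). At least 2-fold differences from mock were counted for 270 genes up and 14 down of 13924 in WT, and for 464 up and 52 down of 14027 in MyD88KO. At least 4-fold rises numbered 102 and 170. The shared response in limma held 776 genes that rose and 338 that fell, of which 334 and 12 were also at least 2-fold.

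The other genes with the largest shared rises were antiviral effectors and regulators of the interferon response. They were Usp18, which limits interferon signalling, Rsad2, the antiviral enzyme viperin, Oasl1, Ifih1, the RNA sensor MDA5, Ifi205, and the interferon-inducible GTPases Gbp7, Iigp1 and Igtp, with fitted log2 changes between 5.95 for Ifih1 (± 0.12, limma adjusted p = 6.05e-06) and 6.99 for Ifi205 (± 0.19, limma adjusted p = 1.06e-05). Isg15, a ubiquitin-like modifier, changed by 4.27 ± 0.23 (limma adjusted p = 0.000168). Of named genes, 4 fell at least 2-fold in both genotypes. Trib2, a pseudokinase gene, fell by 2.02 ± 0.25 (limma adjusted p = 0.00571), Jag1, a Notch ligand, by 1.49 ± 0.21 (0.0086), Edn1, the vasoconstrictor endothelin 1, fell by 1.43 ± 0.12 (0.00105), and Adm, the vasodilator adrenomedullin, fell by 1.07 ± 0.08 (0.000804). Across 14346 genes, which are not independent replicates, the changes in WT and MyD88KO had a Pearson r of 0.827 and a Spearman rho of 0.487. Of 273 genes up in WT and 465 up in MyD88KO, 244 were up in both, against 8.85 for independent lists.

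Among fixed lists, 45 of 47 measured interferon-stimulated genes rose at least 2-fold in WT and 46 in MyD88KO, with medians of 3.45 and 3.88 (percentile 100 of random lists in both). In limma 45 of 47 passed over all genes and 47 when adjusted over the list alone. Interferon-inducible GTPases, which attack pathogen vacuoles, had medians of 2.48 in WT and 3.75 in MyD88KO, with 8 and 10 of 13 measured past 2-fold. In limma 10 of 10 tested rose, with 10 when adjusted over the list alone, but the filter on the brightest array favours members that were induced. In the antigen presentation list 16 of 17 rose, with 16 when adjusted over the list alone, among them Cd274, the checkpoint ligand PD-L1 (5.39 in WT, 5.87 in MyD88KO), and Tap1, a peptide transporter (3.04, 4.18). Of 23 chemokines 8 rose, and 10 rose and 1 fell when adjusted over the list alone. Ccl2 and Ccl7, which attract monocytes, rose by 4.22 and 4.19 in WT, and Cxcl9 by 5.28 in MyD88KO. NF-kB targets rose in 4 of 33 members, and in 13 when adjusted over the list alone, with medians of 0.39 and 0.60. Il6 differed from mock by 2.83 in WT and 3.71 in MyD88KO, and Tnf by 2.58 in WT.

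Genes of the sensing pathways also responded to dsDNA. Of 13 cytosolic nucleic acid sensing components 6 rose in limma, with 6 when adjusted over the list alone. They included Ifi204 (4.31 in WT, 5.34 in MyD88KO), Zbp1, a sensor of Z-form nucleic acid (1.98, 3.53), and Adar, an RNA-editing enzyme (1.67, 1.96). Of 20 Toll-like receptor pathway components 3 rose, with 3 when adjusted over the list alone, and Tlr3, the receptor of double-stranded RNA, rose by 3.63 and 5.54. Of 10 interferon genes tested 2 rose, with 4 when adjusted over the list alone, and the signals of Ifna4 differed from mock by 0.62 in WT and 1.39 in MyD88KO. Of 27 immediate early genes 11 rose and 1 fell, with 13 and 5 when adjusted over the list alone. Atf3, a stress-induced transcription factor gene, rose by 3.17 and 2.70, and Egr1 by 1.22 and 1.55. With 1 of 5 arrays left out in turn, the count of the shared response was 735 without the WT dsDNA array, 270 without the MyD88KO dsDNA array and 280 without the WT LPS, the SKO LPS or the SKO mock array, against 1114 with all, and 638 without the intensity trend.

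**Figure D2:**
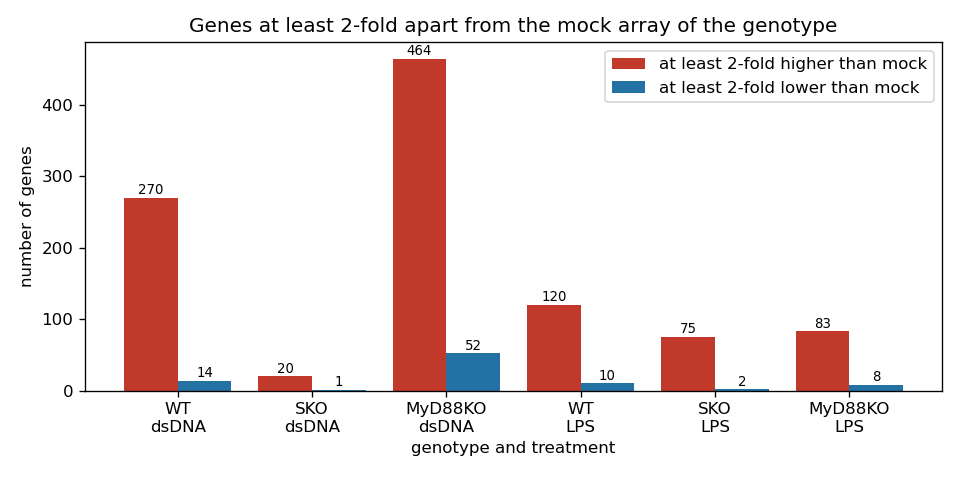
Number of genes (vertical axis, from 0) at least 2-fold higher (red) or lower (blue) than the mock array of the same genotype, for each genotype and treatment, with 1 array on each side of a difference. The counts of higher genes with dsDNA were 270 in WT, 20 in SKO and 464 in MyD88KO, and with LPS 120, 75 and 83.

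In SKO cells dsDNA gave 20 genes at least 2-fold up and 1 down of 13965 genes. The largest rises were of Ifit1 (2.81), Cxcl10 (1.87), Prl8a9, a prolactin family gene (1.87), Usp18 (1.78) and Rtp4 (1.72), and the fall was of Zfp772 (-1.22), a zinc finger gene with signals under 5 on all arrays. The Ifnb1 signals were 2.77 with mock and 2.58 with dsDNA. In limma the dsDNA effect of SKO rests on 1 dsDNA array, and the spread includes the gap between the LPS responses of WT and SKO. A lack of calls there is thus no evidence against a rise. The limma fit of dsDNA in SKO called 0 genes, with 508 at an unadjusted p under 0.05 and 0 with robust eBayes. Interferon-stimulated genes had a median of 0.38 in SKO (percentile 100), and 10 of 47 rose at least 2-fold. Over all genes 0 of the 47 passed, and 7 when adjusted over the list alone. The GTPases had a median of 0.41, with Irgm2 (1.28), Gbp7 (1.27) and Igtp (1.25) past 2-fold. Medians of antigen presentation genes, chemokines and NF-kB targets were 0.05, 0.00 and 0.05. Of 270 genes up in WT and 21 up in SKO, 16 were up in both, against 0.4 for independent lists.

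Between arrays, without a test, NF-kB targets responded more to dsDNA in WT than in SKO by a median of 0.37, in 28 of 34 members. In MyD88KO they responded more than in SKO by 0.57, in 31 (percentile 100 in both). For chemokines these medians were 0.44 and 1.24. The difference was then tested in limma. There the shared LPS effect enters the fitted SKO mock level. The fitted NF-kB median in SKO was 0.27, against 0.05 between arrays, and the fitted chemokine median was 0.39, against 0.001. Counts for these lists may thus understate the difference. For genes with a larger LPS response in SKO than in WT, such as Cxcl10, the fitted difference may be too large. Cmpk2 responded more in the STING-sufficient genotypes than in SKO by 6.40 ± 0.31 (limma adjusted p = 0.000479), Oasl1 by 5.71 ± 0.25 (0.000285), and Iigp1 by 5.50 ± 0.37 (0.00168). Ifit3b, Ifi205, Ifih1, Gbp7 and Oasl2 differed by 5.30 to 5.64, Cxcl10 by 5.19 ± 0.33 (0.00145), Ccl5 by 5.24 ± 0.49 (0.00572) and Ifnb1 by 2.69 ± 0.27 (0.00846). In all, 184 genes had a larger and 6 a lower response in the STING-sufficient genotypes. Of the 47 interferon-stimulated genes, 40 differed over all genes and 45 when adjusted over the list alone. For GTPases these counts were 7 and 10 of 10, for antigen presentation 3 and 17 of 17, for chemokines 3 and 7 of 23, and for NF-kB targets 0 and 0 of 33. Among genes with a lower response in the STING-sufficient genotypes were Adm (-1.14 ± 0.13, limma adjusted p = 0.0134), S1pr3, a sphingosine phosphate receptor (-1.03 ± 0.16, 0.0407), Epha2, an ephrin receptor (-0.94 ± 0.14, 0.0334), and Efna4, an ephrin (-0.91 ± 0.15, 0.0494). The count of 190 was 236 without the WT dsDNA array, 66 without the MyD88KO dsDNA array, 20 without the WT LPS or the SKO LPS array and 14 without the SKO mock array, and 84 without the intensity trend.

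**Figure D3:**
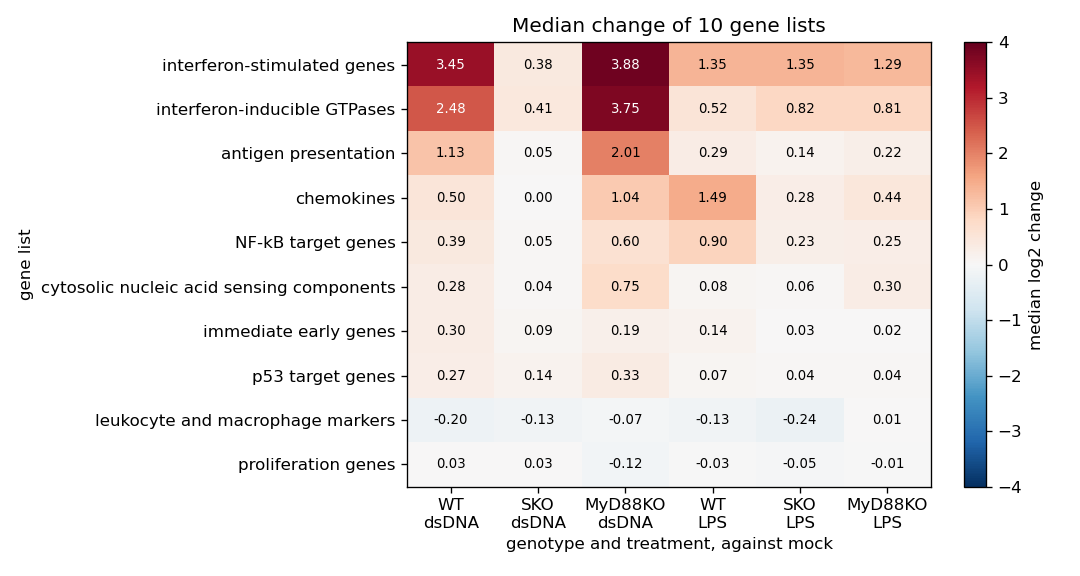
Median log2 change against mock (colour and printed value) of 10 gene lists (vertical axis) for each genotype and treatment (horizontal axis), over the members measured. The interferon-stimulated genes had medians of 3.45, 0.38 and 3.88 with dsDNA in WT, SKO and MyD88KO and between 1.29 and 1.35 with LPS, and the NF-kB targets with LPS had 0.90 in WT, 0.23 in SKO and 0.25 in MyD88KO.

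LPS raised interferon-stimulated genes and Il1b in the MyD88-sufficient genotypes, WT and SKO. Il1b and Il1a, the interleukin 1 genes, differed from mock by 6.06 and 5.95 in WT and by 3.14 and 2.38 in SKO. Ifit1 rose by 3.29 and 5.43, Cxcl10 by 3.55 and 4.57, and Usp18 by 3.78 and 4.12. Ccl3, a chemokine gene, differed from mock by 5.44 in WT and 1.18 in SKO, and Tnf, the tumour necrosis factor gene, by 4.62 in WT. At least 2-fold differences were counted for 120 genes up and 10 down of 13887 in WT, and for 75 up and 2 down of 13985 in SKO. The shared LPS response in limma held 48 genes that rose and 1 that fell, 43 of the former at least 2-fold. Usp18 (4.06 ± 0.19, limma adjusted p = 0.000881), Ifi205 (4.15 ± 0.19, 0.000881), Cmpk2 (3.82 ± 0.19, 0.00105), Cxcl10 (4.04 ± 0.20, 0.00105), Rtp4, Ifi204, Rsad2, Ifit1 and Il1b (4.66 ± 0.57, 0.0343) passed. Il1a (adjusted p = 0.126 in limma), Tnf (0.253) and Ccl3 (0.455), whose differences from mock were larger in WT than in SKO, did not. No gene past 2-fold in both genotypes fell.

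Of the fixed lists with LPS, interferon-stimulated genes had medians of 1.35 in WT and 1.35 in SKO, with 24 and 32 members past 2-fold. In limma 27 of 47 rose over all genes and 40 when adjusted over the list alone, and for GTPases 6 of 10 and 7 when adjusted over the list alone. Chemokines had medians of 1.49 in WT and 0.28 in SKO, with 16 and 4 members past 2-fold. Ccl20 differed from mock by 3.68 and Cxcl3 by 3.61 in WT, and neither passed for the shared response (limma adjusted p = 0.668 and 0.0589). In limma 2 of 23 chemokines rose and 13 when adjusted over the list alone. NF-kB targets had medians of 0.90 and 0.23, with 15 and 4 members past 2-fold, and 1 of 33 rose over all genes and 25 when adjusted over the list alone. In the mock arrays several of these genes stood higher in SKO than in WT, with Ccl3 at 9.57 against 5.53, Ccl20 at 8.05 against 5.64, Saa3, an acute phase gene, at 7.88 against 4.18 and Il6 at 7.26 against 4.77. Their LPS levels were 10.75 against 10.97, 8.63 against 9.32, 8.25 against 7.54 and 8.44 against 7.31. The median leukocyte and macrophage marker differed between these mock arrays by 0.47, and its LPS minus mock median was -0.13 in WT and -0.24 in SKO. Ifnb1 had signals of 2.73 in WT and 2.98 in SKO with LPS, close to mock. Of 123 genes up in WT and 75 up in SKO, 56 were up in both, which share no array, against 0.65 for independent lists, with a Pearson r across genes of 0.447. The count of 49 was 4 without the WT dsDNA or the MyD88KO dsDNA array, 5 without the WT LPS array and 12 without the SKO LPS or the SKO mock array, and 29 without the intensity trend.

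In MyD88KO cells LPS raised interferon-inducible genes, with 83 genes at least 2-fold up and 8 down of 13955. Usp18 rose by 4.38, Cmpk2 by 3.71, Ifi205 by 3.69 and Rtp4 by 3.13, and in limma Usp18, Cmpk2 and Ifi205 each passed with an adjusted p of 0.0158 and Rtp4 with 0.0399. Acod1, the itaconate-producing enzyme gene, differed from mock by 3.56 and did not pass (limma adjusted p = 0.536). The largest falls were of Olfr446 (-1.15), Hpgd (-1.03) and Kcnk9 (-1.02), genes with mock signals under 5. Interferon-stimulated genes had a median of 1.29, with 25 of 47 past 2-fold, and 9 rose in limma over all genes, while 33 rose and 1 fell when adjusted over the list alone. GTPases had a median of 0.81, with 0 of 10 passing over all genes and 6 when adjusted over the list alone. Chemokines and NF-kB targets had medians of 0.44 and 0.25, with 4 of 24 and 1 of 34 members past 2-fold. Muscle markers had a median of -0.39 (percentile 0), against -0.07 in WT and -0.02 in SKO, with 0 of 14 past 2-fold. In limma 0 of the 14 passed over all genes, and 1 rose and 2 fell when adjusted over the list alone. Il1b differed from mock by 0.88, Il1a by 0.72, Cxcl1 by -0.28 and Tnf by 1.02. Of 122 genes up in WT and 84 up in MyD88KO, 54 were up in both, against 0.72 for independent lists. The limma fit called 11 genes, all up, with 4 without the dim filter, 4 without the WT LPS, the SKO LPS or the SKO mock array, and 0 without the intensity trend or without either dsDNA array of the STING-sufficient genotypes.

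For the difference between the LPS responses of MyD88-sufficient and MyD88KO cells, limma called 0 genes, with 765 at an unadjusted p under 0.05 and 0 with robust eBayes. The lowest adjusted p was 0.869. By size, which is not a call, the differences toward the MyD88-sufficient genotypes were led by Il1b (3.88 ± 0.91), Il1a (3.45 ± 1.09), Cxcl3 (2.39 ± 0.62), Ccl20 (2.22 ± 1.11), Ccl3 (2.19 ± 1.34), Il12b, an interleukin 12 subunit gene (2.12 ± 0.70), Cxcl1, a neutrophil attractant (2.07 ± 0.55), and Tnf (2.02 ± 0.95). Those toward MyD88KO were Zfp772, Gzmd, Aoc3 and Ms4a14, between -1.72 and -1.30. In each of the 8 genes from Il1b to Tnf the difference from mock was larger in WT than in SKO, with 5.44 and 1.18 for Ccl3, and this spread enters the test. Set against MyD88KO one genotype at a time, without a test, NF-kB targets responded more in WT by a median of 0.64 and in 33 of 34 members (percentile 100), and more in SKO by 0.04 and in 18 of 34. Chemokines responded more in WT by a median of 0.70 and in 19 of 24 members, but less in SKO, by -0.14, with 6 of 24 members larger than in MyD88KO. The high SKO mock levels enter these differences. Between the LPS arrays themselves, chemokines differed from WT by a median of -0.14 in SKO and -0.94 in MyD88KO, with 1 and 11 of 24 lower at least 2-fold, and NF-kB targets by -0.04 and -0.63, with 4 and 12 of 34 lower. For interferon-stimulated genes the medians of the response differences were -0.05 and 0.29.

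Compared directly without the mock arrays, dsDNA and LPS arrays of WT differed at least 2-fold in 213 genes higher with dsDNA and 57 higher with LPS. Higher with dsDNA were Oasl1 (5.26), Il33, an epithelial and stromal alarmin gene (4.53), Mx2, an antiviral GTPase gene (4.15), Cmpk2 (4.10), Ifih1 (3.96) and Ifit1 (3.92). Higher with LPS were Il1b (-6.39), Il1a (-5.65), Saa3 (-3.53), Clec4e, a receptor of mycobacterial glycolipid (-3.35), Ccl20 (-3.20) and Cxcl3 (-3.09). In the WT arrays the median dsDNA minus LPS difference was 1.91 for interferon-stimulated genes, with 41 of 47 members at least 2-fold higher with dsDNA, and -0.43 for NF-kB targets. In MyD88KO 391 genes were higher with dsDNA and 76 with LPS. In SKO 0 genes were at least 2-fold higher with dsDNA and 65 were higher with LPS, and the difference for Ifit1 was -2.62 and for Cxcl10 -2.70.

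Among the genes with the largest differences between SKO and WT cells under all 3 treatments, Mmp13, Mmp3 and Mmp10, genes of secreted proteases that degrade extracellular matrix, were higher by 2.60 ± 0.48 (limma adjusted p = 0.0438), 2.43 ± 0.20 (0.0024) and 2.11 ± 0.27 (0.0111). Marco, a scavenger receptor of macrophages, was higher by 2.52 ± 0.13 (0.000307), Cd36, a fatty acid and lipoprotein receptor, by 2.22 ± 0.10 (0.000179), Slc13a3, a dicarboxylate transporter gene, by 2.39 ± 0.11 (0.000184), and Tnip3 by 2.30 ± 0.21 (0.00351). Vmn2r125, a vomeronasal receptor gene, was higher by 6.80 ± 0.21 (7.44e-05), with signals between 9.17 and 9.55 in SKO and between 1.81 and 2.82 elsewhere. Of 29 fibroblast and extracellular matrix genes 0 were higher and 1 was lower at any size over all genes in limma, and 3 were higher and 8 lower when adjusted over the list alone. After Sting1, the named genes lower in SKO were Fxyd6 (-1.64 ± 0.06, limma adjusted p = 7.98e-05), Aspn, a matrix proteoglycan gene (-1.63), Slc2a3, a glucose transporter gene (-1.40), Mymk, which is needed for myoblast fusion (-1.39), Hhip, a hedgehog inhibitor (-1.37), Bex1 (-1.36) and Sema6a (-1.26). The limma fit called 47 genes higher and 16 lower, and 26 were higher and 9 lower at least 2-fold in each of the 3 treatments. Without the mock arrays of both genotypes the count was 3.

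In the mock arrays alone, 107 genes were at least 2-fold higher and 23 lower in SKO than in WT. NF-kB targets had a median difference of 0.65 (percentile 100) with 11 of 34 past 2-fold, among them Saa3 (3.69), Zc3h12a (2.15) and Il1a (2.13). Chemokines had 0.49 with 8 of 24, led by Ccl3 (4.04) and Ccl2 (3.90), and interferon-stimulated genes 0.26 with 4 of 47. Leukocyte and macrophage markers had 0.47 with 3 of 18, led by Adgre1, the macrophage antigen F4/80 (1.97), Cd53 (1.21) and Lyz2, lysozyme (1.01). In limma over the 3 treatments, 342 of 14737 genes passed at any size. Of these markers 6 of 18 were higher at any size, 3 of them at least 2-fold, with 10 when adjusted over the list alone. Muscle markers had -0.49, led by Myh3, embryonic myosin (-1.64), Mymk (-1.58) and Actc1 (-1.22), and 6 of 14 were lower in limma at any size, 3 of them at least 2-fold, with 9 when adjusted over the list alone. At any size NF-kB targets were higher in 1 of 33 over the treatments, with 6 when adjusted over the list alone, and immediate early genes lower in 2 of 27, with 7 when adjusted over the list alone.

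MyD88KO cells differed from WT cells in more genes, 249 higher and 194 lower in limma at 2-fold or more, with 146 and 119 past 2-fold under each of the 3 treatments. Higher were Dpt, a dermal matrix gene (3.88 ± 0.09, limma adjusted p = 1.76e-06), Crabp1, a retinoic acid binding protein gene (3.53 ± 0.06, 5.53e-07), Col6a3, a collagen chain gene (2.96 ± 0.09, 4.74e-06), Pdgfra, a growth factor receptor of mesenchymal cells (2.43 ± 0.13, 4.36e-05), S100a4 (2.32), S1pr3 (2.54), Gpr149 (2.56) and U90926 (3.28). Lower were Rgs5, a marker of pericytes (-4.69 ± 0.21, 1.99e-05), Cldn4, a tight junction gene (-3.78 ± 0.10, 3.02e-06), Dgkk (-3.39), Bex1 (-3.28), Perp, a p53-induced gene (-3.00 ± 0.10, 8.11e-06), Tnfsf18 (-2.81) and the Y-linked genes Eif2s3y (-3.72) and Uty (-3.32).

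In limma 2867 of 14737 genes differed between MyD88KO and WT at any size, so list counts at any size are given with those at least 2-fold. Proliferation genes were higher in MyD88KO, with a median of 1.22 in the mock arrays (percentile 100), 21 of 27 past 2-fold, and 27 of 27 passing limma at any size, 21 of them at least 2-fold, with 27 when adjusted over the list alone. Ccna2, a cyclin gene, was higher by 1.74, Birc5, the survivin gene, by 1.57 and Mki67, which encodes the Ki-67 antigen, by 1.54. p53 targets were lower, with a median of -0.58 (percentile 0) and 12 of 18 passing at any size, 4 of them at least 2-fold, and 14 when adjusted over the list alone, led by Perp (-2.79), Pmaip1, the cell death gene Noxa (-2.13), Trp53inp1 (-1.55) and Fas, a death receptor gene (-1.51). Cholesterol biosynthesis genes had a median of 0.75, with 13 of 17 higher at any size, 4 of them at least 2-fold, and 14 when adjusted over the list alone, among them Lss, lanosterol synthase (1.24). Muscle markers had -0.46, with 11 of 14 lower at any size, 5 of them at least 2-fold, and 11 when adjusted over the list alone. Of 29 fibroblast and extracellular matrix genes 15 were higher and 6 lower at any size, 6 and 1 of them at least 2-fold, with 18 and 6 when adjusted over the list alone, and Thy1 was higher by 2.06. The sex-linked list, of 4 genes, had 3 Y-linked genes lower and Xist higher by 1.70 in the mock arrays, and all 4 passed limma and were at least 2-fold apart, with 4 when adjusted over the list alone. Leukocyte and macrophage markers had a median of 0.30, with 6 of 18 higher at any size, 0 of them at least 2-fold, and 10 when adjusted over the list alone. NF-kB targets and interferon-stimulated genes had mock medians of 0.02 and 0.17.

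**Figure D4:**
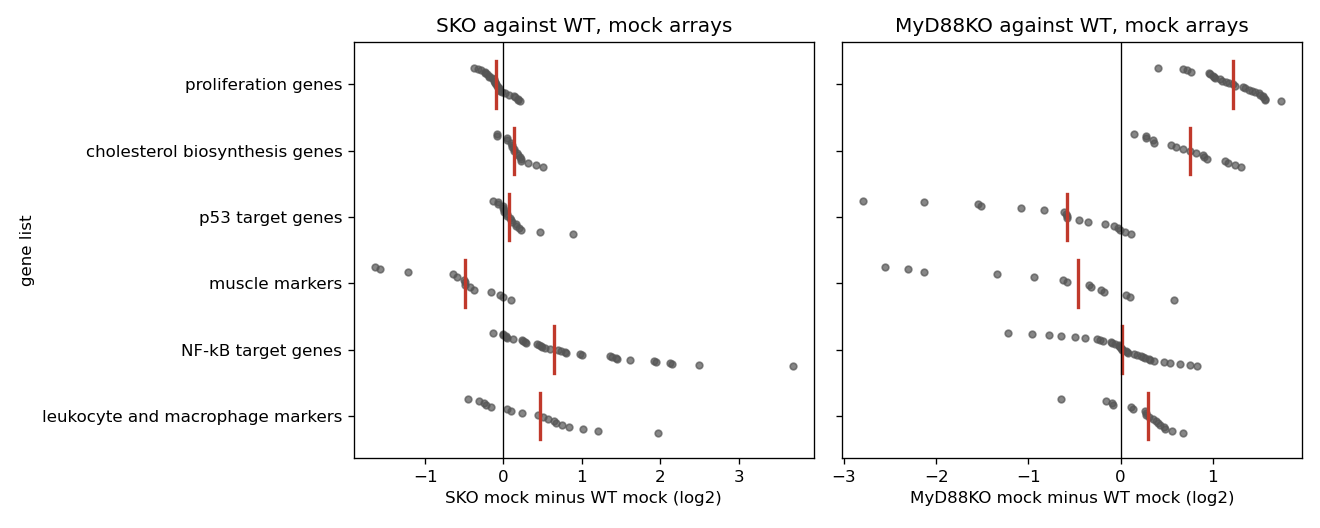
Log2 difference of each member (grey points) of 6 gene lists between the SKO and WT mock arrays (left) and between the MyD88KO and WT mock arrays (right), with the list median as a red line and 1 array per group. The NF-kB targets had a median of 0.65 in SKO and 0.02 in MyD88KO, and the proliferation genes -0.10 and 1.22.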

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

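The tests of endotoxin in the DNA, of the SKO mock array, of leukocytes, of p53 activity and of other splits of the arrays were chosen after the results were seen. The difference of the dsDNA response between STING-sufficient genotypes and SKO was tested in limma and called 190 genes. The largest differences were 6.40 for Cmpk2, 5.71 for Oasl1, 5.64 for Ifit3b, 5.50 for Iigp1, 5.47 for Ifi205, 5.47 for Ifih1, 5.32 for Gbp7 and 5.30 for Oasl2, and those of opposite sign were -1.14 for Adm, -1.03 for S1pr3, -0.94 for Epha2 and -0.91 for Efna4. Probe sets outside the comparisons also responded, with 24 probe sets of several gene symbols and 34 without a symbol at least 2-fold higher with dsDNA than with mock in both WT and MyD88KO. Their median changes in SKO were 0.23 and 0.15.

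A smaller dsDNA response was left in SKO, with 20 genes at least 2-fold up, 10 of them interferon-stimulated genes. The median log2 change of all 47 measured interferon-stimulated genes was 28.4% of their median log2 change with LPS in SKO. This is a ratio of log2 values, not of linear signals. Endotoxin in the DNA, if it raised LPS genes by one share, is not decided by 5 genes selected on the LPS arrays, with a median of 0.271 (bootstrap interval -0.031 to 0.367) where 0.301 was predicted, because dsDNA itself raised 4 of them in WT, among them Bst2 (2.38) and Il6 (2.83), and any remaining dsDNA response would give the same rise. A set tried earlier held 4 genes selected as not raised by dsDNA in WT and MyD88KO. Its median was -0.015 in SKO where 0.63 was predicted (Il1b at -0.35 against 3.14 with LPS, Il12b at -0.03 against 1.02). This set was replaced because its selection uses the dsDNA arrays. Endotoxin in the DNA could raise LPS genes in WT and MyD88KO too, so the selection favours genes without a rise and its values do not decide. No doses of LPS were compared, and a dose that raises interferon-stimulated genes and not these also stays open. RNA of a STING-sufficient dsDNA sample mixed into the SKO dsDNA sample was examined as a share of linear signals. Over 62 dsDNA-induced genes that LPS raises in SKO the median share was 4.38%. Mixing needs 1 share for all genes, but the shares of single genes were spread. They were 0.72% for Oasl1 and 1.11% for Cmpk2, against 5.98% for Isg15 and 7.24% for Usp18. How far compressed signals and single arrays add to this spread was not tested. The 19 dsDNA-induced genes that LPS does not raise in SKO gave 1.81%, which met the bound set before the test. The bootstrap interval added afterwards (-0.94% to 4.20%) did not stay under that bound. Such RNA would also carry Sting1 (8.57 in WT with dsDNA). A share of 4.38% predicted a Sting1 signal of 5.28 in the SKO dsDNA array. The signal there was lower, at 4.60, against 4.54 with mock and 3.78 with LPS. Sting1 is dim in SKO, where differences are understated, and smaller shares were not set against it, so mixing stays open. Whether the mock cells received transfection reagent is not given, so an effect of the transfection itself also stays open. DNA sensing without STING is an open biological explanation that was not tested.

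Inflammatory genes stood higher in SKO before treatment. A disturbance of the SKO mock array alone is argued against, since the 107 genes higher in SKO mock changed by a median of -0.055 from SKO mock to SKO dsDNA. More leukocytes in the SKO cultures may account for part, since the median of 18 leukocyte markers was 0.472 (percentile 100), with Adgre1 (1.97) and Cd53 (1.21) higher, but 5 markers were lower and 15 of the 18 passed the dim filter in the WT mock array too, so this stays open. A state like the MyD88-dependent part of the LPS response is a candidate explanation, tested between the SKO and MyD88KO mock arrays. The 43 genes that LPS raised in WT and under 1.5-fold in MyD88KO were higher in SKO mock by a median of 0.966. But 52 genes raised in both were higher too, by 0.412 (percentile 100 for each set), so a part that does not need MyD88 stays open. The MyD88KO mock array also entered the choice of genes. A low value there favours the 52 genes, so their difference is not independent of the selection. An effect of the absence of STING stays open as a biological explanation, untested, since genotype and preparation of cells go together.

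MyD88KO cells differed from WT in 443 genes. The 3 measured Y-linked genes were lower and Xist was higher in MyD88KO, the directions that a difference in sex of the cells would give. Genes on chromosomes X and Y account for few of the 443, with 5.9% (26) there, where 3.2% of the tested genes lie. Effects of sex on genes of other chromosomes were not examined and stay open. For DNA kept around the targeted locus, 0.68% (3) were among the 163 nearest tested genes around Myd88, which make up 1.11% of the genes tested. Called genes were thus not concentrated near Myd88. The 163 genes could not have made up most of the 443 whatever their calls. Effects of kept DNA on genes elsewhere were not examined and stay open. Lower p53 activity and faster growth of this preparation of cells is a candidate explanation, with a p53 target median of -0.581 and a proliferation median of 1.22 in the mock arrays, and cannot be told apart from an effect of MyD88 with 1 array per group.

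For SKO against WT the real split of the 6 arrays gave 63 genes and the highest other split 2, and for MyD88KO against WT the real split gave 443 and the highest other 0. The 10 splits are too few for a share under 0.05, and 1 of them, the real split, gave as many genes in each comparison.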

How the results depend on the processing

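The fits without the SKO mock array and with robust eBayes were chosen after the data were seen, and the other alternatives before. No result changed direction in any alternative. No pairing of replicates was possible because each group holds 1 array and every label carries replicate number 1. Genotypes were compared within treatments by the additive genotype model. With a 1.5-fold threshold, dsDNA against mock counted 765 genes in WT, 150 in SKO and 1317 in MyD88KO, LPS against mock 368, 191 and 435, and dsDNA against LPS 729, 215 and 1276, a looser limit by construction. Without the dim filter, 39 genes in SKO differed between dsDNA and mock and limma called 4 for LPS in MyD88KO, and with the filter at the 75th percentile the 2-fold counts were 8 for dsDNA in SKO and 41 for LPS in MyD88KO. Without the intensity trend limma called 638 genes for the shared dsDNA response, 84 for its difference from SKO, 29 for the shared LPS response and 0 for LPS in MyD88KO. The additive average over the 3 genotypes called 0 genes for dsDNA (2189 at an unadjusted p under 0.05) and 0 for LPS (697), since it counts differences between genotypes as spread. With 1 array left out, which leaves 1 residual degree of freedom, the counts ran from 270 to 735 for the shared dsDNA response, from 14 to 236 for the difference, from 4 to 12 for the shared LPS response, and from 0 to 4 for LPS in MyD88KO. SKO against WT ran from 3 without the mock arrays to 67 without the dsDNA arrays, and MyD88KO against WT from 388 to 485. The median of the interferon-stimulated genes was 3.47 with cyclic loess for dsDNA in WT, and 1.37 in WT and 1.33 in MyD88KO for LPS with arrays shifted to the same median. Over members past the dim filter it was 0.47 for dsDNA in SKO, 1.45, 1.48 and 1.36 for LPS in WT, SKO and MyD88KO, and 0.29 for SKO against WT mock, fewer members by construction. For the other changes of a count or median the cause was not tested. Robust eBayes called 1159, 213, 43, 11, 58 and 434 genes for the responses and genotype differences in the order above. Low signals limit Ifnb1 and other dim genes, whose changes are compressed.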

Other observations

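The tests of differences between list medians of the genotypes were chosen after the data were seen. p53 target genes had dsDNA minus mock medians of 0.27 in WT, 0.33 in MyD88KO and 0.14 in SKO (percentile 100 in each), against 0.07, 0.04 and 0.04 with LPS. In limma 7 of 18 rose in the shared dsDNA response, 12 when adjusted over the list alone, and in SKO 0 rose over all genes and 3 when adjusted over the list alone. Trp53inp1, a p53-induced autophagy gene, differed from mock by 0.92 in WT, 1.40 in MyD88KO and 0.60 in SKO, and Mdm2, the p53 ubiquitin ligase gene, by 0.34 in SKO. The difference of this list's response between STING-sufficient genotypes and SKO had 0 of 18 calls and 0 when adjusted over the list alone, with medians of 0.16 for WT minus SKO and 0.22 for MyD88KO minus SKO. Cholesterol biosynthesis genes had dsDNA minus mock medians of -0.09 in WT, -0.14 in MyD88KO and 0.07 in SKO, with Sqle at -0.66 in MyD88KO and 0 of 17 called, 0 when adjusted over the list alone. Slc7a11, the cystine transporter gene of the integrated stress list, differed between LPS and mock by 1.79 in WT, 0.88 in SKO and 0.32 in MyD88KO, and this list had medians of 0.01, 0.00 and -0.04.

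The LPS minus mock difference of interferon-stimulated genes was smaller in WT than in SKO, by a median of -0.33 with 14 of 47 members larger in WT (percentile 0), and that of chemokines and NF-kB targets was larger in WT, by 1.11 and 0.72 (percentile 100). These differences were not tested with replicates. Proliferation genes had dsDNA minus mock medians of 0.03 in WT and -0.12 in MyD88KO. Markers of other cell types had dsDNA minus mock medians in WT and MyD88KO of -0.20 and -0.07 for leukocytes and macrophages (percentile 0.02 in WT), -0.12 and -0.11 for muscle (percentile 2.66 in WT), 0.00 and -0.02 for epithelium, 0.01 and 0.05 for endothelium, 0.03 and -0.11 for neural and glial cells, -0.01 and -0.23 for chondrocytes and osteoblasts, and -0.04 and 0.09 for adipocytes. With LPS the medians in WT, SKO and MyD88KO were -0.07, -0.02 and -0.39 for muscle (percentile 0 in MyD88KO), and -0.13, -0.24 and 0.01 for leukocytes and macrophages, and the other cell types lay between -0.15 and 0.07. The muscle response differed from that of MyD88KO by a median of 0.28 in WT and 0.40 in SKO (percentile 99.95 and 100), and the test of MyD88-sufficient minus MyD88KO had 0 of 14 calls over all genes and 3 higher and 1 lower when adjusted over the list alone. In the mock arrays of MyD88KO against WT the glycolysis and hypoxia genes had a median of -0.09, and 5 of 18 were lower in limma at any size, 5 when adjusted over the list alone, but 0 of them at least 2-fold. That share of 27.8% was close to the 19.5% of all genes that passed at any size. In the same arrays the medians were -0.03 for epithelial (percentile 21.55), 0.00 for endothelial (percentile 54.91), -0.09 for neural and glial, 0.19 for chondrocyte and osteoblast, and 0.13 for adipocyte markers. In limma at any size, 0 of 7 epithelial markers were higher and 4 lower, 1 and 2 of 9 endothelial, 1 and 3 of 10 neural, 1 and 2 of 9 chondrocyte, and 1 and 0 of 8 adipocyte markers. When adjusted over the list alone these counts were 0 and 5, 1 and 3, 2 and 5, 1 and 2, and 1 and 0. The largest members, which do not stand for their lists, were Cldn4 (-3.50), Emcn (-1.45) and Kdr (-1.22), Nes (-1.05), and Lpl (1.29), and Col11a1 differed by -1.33.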
